A study of Mus musculus with 8 samples.

How the data were processed

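The samples were 8 sections of mouse skin, 2 in each of 4 groups, imaged on the Xenium platform with a targeted probe panel of 100 genes, 20 negative control probes, 41 negative control codewords and 380 unassigned codewords. Groups, time points (PI-14 and PI-7) and replicate numbers were taken from the labels. Slide numbers were read from the names of the deposited files. The values used were those deposited: per the file headers, each section has a matrix of counts, that is decoded transcripts per feature and segmented cell, and a table of single transcripts with position, cell, overlap with a nucleus and a quality score. The deposited quality score is a Phred-like value of at most 40 per transcript. The deposited counts were whole numbers and not normalised, and their gene totals equalled the number of transcripts in cells with a quality of at least 20 in the transcript table of the same section. Decoding, segmentation and the choice of genes were the authors' own steps, and their settings and software version are not given in the sources used here. Positions were taken as micrometres, the platform's usual unit. Gene symbols were used as the deposited files give them. All 100 symbols were found in the mouse gene table at hand (GRCm38.p6) and 0 by Ensembl identifier, and no genome coordinates are reported.

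Comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The 2 main comparisons were expanded against nonexpanded skin at PI-14 and Yoda1 against no Yoda1 in expanded skin at PI-7. Cells are not replicates, so gene counts were summed over all cells of a section. Sums were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, 1 coefficient for each of the 4 groups over all 8 sections, the quasi-likelihood F test and Benjamini-Hochberg adjustment over the tested genes, with a threshold of 0.05 on the adjusted p. The filter kept 100 genes. Levels are given as CPM. Gene lists with at least 3 tested genes, 11 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count of 2, preset correlation of 0.01), with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data and with fry. The lists were markers of basal keratinocytes, suprabasal keratinocytes, macrophages or monocytes and T or NK cells, and genes of macrophage states, inflammation, glycolysis and hypoxia, lipid metabolism, extracellular matrix, mechanical and YAP-TEAD response, and Wnt, Notch, hedgehog and growth factor signalling. Other lists fixed beforehand had under 3 genes on the panel and were not tested. By camera, lists were tested against the other genes of a panel that the study chose, not against the genome, whereas fry tests a list against no change and compares it with no other genes.

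Named genes were, per main comparison, those past the threshold whose sections did not overlap between groups, up to 12 with the highest and 12 with the lowest log2 fold change. Where under 10 passed, the 10 genes with the smallest p were named as not past the threshold. To these were added the 4 genes with the smallest p of each list, up to 5 per direction past the threshold within a class or else 3 with the smallest p, and Piezo1. Genes named outside this rule are Sprr2a3 in keratinocyte-like cells, Igfbp2 and Lgr5 in Pecam1-led clusters, Epas1 in Pdgfra-led clusters, Krt1, Krt10 and Lor in keratinocyte-like cells with Yoda1, and the macrophage and T or NK markers within macrophage-like cells, the genes in single keratinocyte-like clusters, and Cd163, Adgre1, Ptprc, Pdgfra and Pecam1 in Pecam1-led clusters, which were chosen after their values were seen. The same holds for Fabp5 within macrophage-like cells.

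For cell classes, 70845 cells with at least 10 transcripts were kept. Counts were scaled to the median total, log-transformed, scaled per gene and clipped at 10, and reduced to 30 principal components. A shared-neighbour graph of 15 neighbours was divided by the Leiden method (resolution of 1, 5 iterations, fixed seed), which gave 24 clusters. A cluster was named for a class when at least 3 of the class's markers were raised by at least 1.5-fold and at least 1 lay among its 10 leading genes, with no other class having as many. Keratinocyte-like, macrophage- or monocyte-like and T or NK-like classes could be named. Fibroblast-like and endothelial-like cells could not, since the panel holds 1 marker of each, so the 4 planned tests within them were not run. Clusters with Pdgfra or with Pecam1 among their leading genes were summed in their place, a choice made after the data were examined. No doublet caller was run, since cells were segmented in place, and transcripts of neighbouring cells inside a cell's outline were not removed. Class counts were tested with edgeR, with the section's kept cells as the offset, over 16 classes and unnamed clusters, beside an exact two-sided permutation test. Within a class, gene counts were summed over its cells in each section with at least 20 of them and tested like whole sections. The distance of each macrophage-like cell to the nearest keratinocyte-like cell was summarised by its median per section and compared by an exact two-sided permutation test. Pieces of a section were sets of at least 20 segmented cells linked by distances within 100 µm. The interval of a pooled ratio is an exact 95% binomial interval, and the interval of a correlation across genes comes from Fisher's transformation. Both cover counting or gene-to-gene spread only.

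The tests were tried on simulated counts with known changes, 20 simulations with 20 changed genes each, drawn from the means, totals and spread of the real sections. Each gene had 1 mean and 1 spread, taken over all 8 sections and used for every group. In the data the median gene differed by 0.75 on the log2 scale between the nonexpanded sections, against 0.24 between the expanded sections at PI-14. The values for PI-14 below therefore do not cover a wider spread, or lower counts, in nonexpanded skin. At PI-14, 92.0% of 8-fold and 20.5% of 2-fold changes among 100 genes were recovered in whole sections, and 0.562% of unchanged genes were called. For the Yoda1 comparison these values were 99.0%, 20.0% and 0.625%. Among 99 genes in keratinocyte-like cells, 90.0% of 8-fold and 14.0% of 2-fold changes were recovered at PI-14, and 94.0% and 10.0% for Yoda1. Among 99 genes in macrophage-like cells, 75.5% of 8-fold and 15.0% of 2-fold changes were recovered at PI-14, and 99.5% and 20.5% for Yoda1. The glycolysis and hypoxia list of 14 genes, shifted by 1 on the log2 scale, was called in 100% of simulations in both comparisons. No other list was shifted, and genes were drawn independently of each other. In the real sections the estimated correlation was 0.71 in the basal keratinocyte list and 0.78 in the macrophage list. That value therefore does not measure how well such smaller, correlated lists are recovered. An 8-fold change in a class share was recovered in 30.0% of cases at PI-14 and 35.0% for Yoda1. Differences of 2-fold were thus mostly not detectable at this depth and with 2 sections per group.

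The alternatives, whose effect is given in the closing section, were DESeq2 1.42.0 in place of edgeR, no TMM scaling, no filter, transcripts over nuclei only, all transcripts of quality 20 or more inside cells or not, cells with at least 10 transcripts only, the 4 sections of a comparison alone, the replicate number as a block, the 3 sections on a shared slide, other transcript minimums (5 and 20), other resolutions (0.5 and 2), naming cells by marker counts (at least 3 transcripts of a class and no tie), thinning cells to 10 transcripts, and leaving out each section, with camera on the shared slide under an estimated correlation added after the data were examined. Where a section was left out, its lone partner was assumed to vary like the other groups. Without TMM the median gene moved by 0.25 on the log2 scale at PI-14 and -0.03 for Yoda1. Control features were used only to describe background, and quality scores only as the threshold of 20. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 was used for all other steps.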

Results

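Expression of 100 genes was measured by in situ imaging (Xenium) in 8 sections of mouse skin that was fixed in paraformaldehyde and embedded in paraffin. The sections fell into 4 groups of 2. At the time point labelled PI-14 the groups were expanded skin and nonexpanded skin, and at PI-7 they were expanded skin with Yoda1 and expanded skin without it. The labels do not spell out PI. Yoda1 is a small-molecule agonist of Piezo1, an ion channel opened by mechanical force, and the series title names Piezo1, metabolism, inflammation and skin regeneration. The labels do not say whether the 2 sections of a group came from separate animals, so the p-values below measure only the spread between these sections, which may be technical.

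The sections differed in size and depth. Expanded sections 1 and 2 at PI-14 held 1213851 and 1477864 panel transcripts in cells, against 135833 and 36284 in nonexpanded sections 1 and 2. Yoda1 sections 1 and 2 held 898844 and 754913, and expanded sections 1 and 2 at PI-7 without Yoda1 held 550308 and 942852. The median segmented cell carried 49 and 31 transcripts in the expanded sections at PI-14, 8 and 5 in the nonexpanded sections, 84 and 40 with Yoda1 and 35 and 66 without it. Of 86626 segmented cells, 70845 carried at least 10 transcripts and were kept for cell classes, which left 2595 and 973 cells in the nonexpanded sections and at least 6768 in each other section. A negative control probe drew on average 24.3 and 56.5 counts per 1e6 gene counts in the nonexpanded sections and at most 10.3 in each other section. With 100 genes the average gene lies at 10000 CPM by the scaling alone. The highest negative control probe drew 19 and 12 counts in nonexpanded sections 1 and 2. Myh3 drew 26 and 8 counts there and S100a8 87 and 9. The nonexpanded values of Myh3, and of S100a8 in section 2, thus lie near that probe. Nonexpanded section 2 lay in 4 separate pieces, with cells under 100 µm apart taken as linked, and keratinocyte-like cells (classes below) made up 87.2%, 98.1%, 97.8% and 6.30% of their kept cells. Each other section was 1 piece or 2, and whether nonexpanded section 2 samples the same part of the skin is not given in the sources used here. Expanded section 1 at PI-14 was alone on its slide, as was expanded section 1 without Yoda1 at PI-7, and the other 3 sections of each time point shared a slide. Time point and slide therefore could not be told apart, and a value within a slide rests on 3 sections. The median gene differed between the 2 sections of a group by 0.24 on the log2 scale in expanded skin at PI-14, 0.75 in nonexpanded skin, 0.53 with Yoda1 and 0.28 without it.

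The comparison at PI-14 asked how expanded skin differs from nonexpanded skin. S100a8, Stfa1, Gsdmc and Tnc rose, and Krt15 and Lgr6 fell. S100a8, a calcium-binding alarmin, was 55.4-fold higher (log2 fold change 5.79, SE 0.77, 2 sections per group). Stfa1, a cysteine protease inhibitor, was 12.2-fold higher (log2 3.60, SE 0.39), and Gsdmc, a gasdermin, was 6.98-fold higher (log2 2.80, SE 0.44). Tnc, which encodes the wound matrix protein tenascin C, was 14.7-fold higher (log2 3.88, SE 0.53). Krt15 and Lgr6, markers of basal and hair follicle progenitor cells, were 22.9-fold and 10.4-fold lower (log2 -4.52, SE 0.50, and -3.37, SE 0.69).

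In all, 15 of 100 genes rose and 12 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 40 had an unadjusted p under 0.05. Beside those named, the genes with the highest fold changes were Sprr2a3, a cornified envelope precursor, by 2.88 on the log2 scale (edgeR adjusted p 0.00838), Myh3, an embryonic muscle myosin, by 2.85, and Igfbp2, a binding protein of insulin-like growth factors, by 2.32. Mrc1, Csf1r, Cd163 and Adgre1, genes of macrophages, rose by 1.92, 1.75, 1.73 and 1.72, and Postn, which encodes the matrix protein periostin, by 1.65 (edgeR adjusted p 0.0448). Of 8 fits that each left out 1 section, 7 ended the call of Postn (adjusted p 0.0648 to 0.187), which passed only without nonexpanded section 1, 4 that of Mrc1, 3 those of Myh3, Cd163 and Adgre1, 2 that of Csf1r and 1 those of Sprr2a3 and Igfbp2. Without nonexpanded sections 1 and 2 in turn, Mrc1 stood at 3.10 and 1.28 and Postn at 2.71 and 1.01. The lowest fold changes after Krt15 and Lgr6 were those of the cornified envelope gene Lor (-2.67), the lipid enzyme gene Scd1 (-2.46), the hemidesmosome gene Col17a1 (-2.21), the keratin gene Krt10 (-2.00), the fatty acid synthase gene Fasn (-1.80), the glycolytic gene Pfkm (-1.54), the receptor gene Lrig1 (-1.47), Krt5 (-1.40), the E-cadherin gene Cdh1 (-1.30) and the Hippo pathway effector Yap1 (-1.05). Here 7 of the 8 fits ended the call of Krt5 (adjusted p 0.0518 to 0.187), which passed only without nonexpanded section 1, 5 those of Krt10, Pfkm and Yap1, 3 those of Lor and Scd1, 2 those of Col17a1, Fasn, Lrig1 and Cdh1 and 1 that of Lgr6, and without nonexpanded section 2 Lor stood at -1.55 and Krt10 at -0.96. Normalised S100a8 stood at 28174 ± 10966 CPM in expanded and 475.3 ± 231.4 in nonexpanded sections (SD, n = 2 each). Krt15 stood at 2456 ± 214.3 and 56309 ± 26654 CPM. Piezo1 was lower by -0.71 on the log2 scale and did not pass the test (edgeR adjusted p 0.131), at 3192 ± 13.0 CPM in expanded and 5205 ± 699.1 in nonexpanded sections (SD, n = 2 each).

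**Figure D1:**
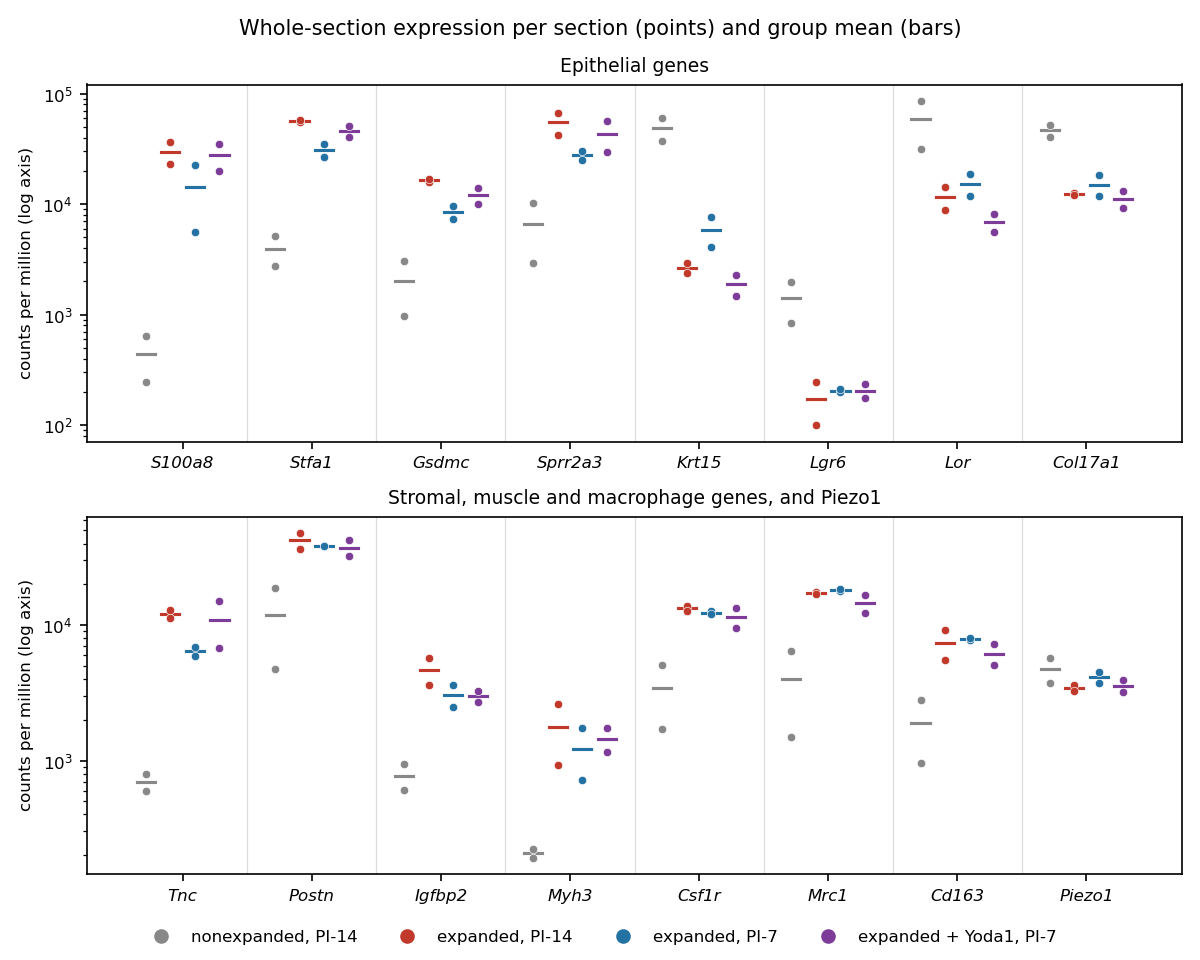
CPM on a log axis for 16 genes summed over whole sections, with a point for each section and a bar for the mean of each group of 2 sections. S100a8 lies at a mean of 28174 in expanded and 475.3 in nonexpanded skin at PI-14, and Krt15 at 2456 and 56309.

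Of the macrophage markers fixed beforehand, 4 of 5 rose (Csf1r, Cd163, Mrc1 and Adgre1), and 5 passed when adjusted over the list alone. The list moved up against the rest of the panel (mean log2 fold change 1.69, camera adjusted p 0.0180, but adjusted p = 0.529 with an estimated correlation), with a mean of 2.55 without nonexpanded section 1 and 1.18 without nonexpanded section 2, and the macrophage-like share of kept cells was 28.2% ± 1.94 in expanded and 6.82% ± 5.72 in nonexpanded sections (SD, n = 2 each). All 3 genes of the macrophage state list, of which 2 are also in the marker list, rose, namely Cd163, Mrc1 and the fatty acid-binding protein gene Fabp5 (1.31), and 3 passed when adjusted over the list alone (camera adjusted p 0.0541; 0.0461 by fry, which tests a list against no change and not against the rest of the panel). Keratinocyte-like cells held 51997 of 59296 and 62405 of 73940 Fabp5 transcripts of expanded sections 1 and 2. Within macrophage-like cells Fabp5 did not pass (0.41, edgeR adjusted p 0.699). Its rise in whole sections is therefore not a measure of macrophage state. Leaving out a section ended the call of Fabp5 in 7 of 8 fits (adjusted p 0.0530 to 0.206), all but that without nonexpanded section 1, of Mrc1 in 4 and of Cd163 in 3. Of the basal keratinocyte genes, 3 of 4 fell (Krt15, Col17a1 and Krt5), Krt14 did not pass (-0.46), and 3 passed when adjusted over the list alone. This list moved down (mean -2.15, camera adjusted p 0.0235, but adjusted p = 0.529 with an estimated correlation), beside a keratinocyte-like share of 25.4% ± 2.18 in expanded and 64.1% ± 26.2 in nonexpanded sections (SD, n = 2 each). Of the suprabasal genes, Lor and Krt10 fell, Ivl (-1.12) and Krt1 (-0.77) did not pass, and 2 passed when adjusted over the list alone (camera adjusted p 0.0786).

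Of 7 lipid metabolism genes, 6 were lower and 1 higher (mean -1.12): Fasn and Scd1 fell, Fabp5 rose, and 4 did not pass, among them the acyl-CoA synthetase gene Acsl1 (-0.92). Over this list alone, 3 genes passed, and the list did not pass by camera (adjusted p 0.117) but did by fry, as a fall against no change (adjusted p 0.0461). Of the extracellular matrix genes, Tnc and Postn rose (the call of Postn ended in 7 of 8 left-out fits), Col17a1 fell and the basement membrane collagen gene Col4a1 did not pass (-0.12), with 3 past when adjusted over the list alone (camera adjusted p 0.497). Of 14 glycolysis and hypoxia genes, Pfkm fell and 13 did not pass, among them Vegfa (-1.05), Hif1a (0.73) and Ldhb (-1.54), and 0 passed when adjusted over the list alone (camera adjusted p 0.475). Yap1 fell among 6 mechanical and YAP-TEAD response genes, while Piezo1, Wwtr1 (-0.74) and the integrin gene Itgb1 (0.72) did not pass, and 1 passed when adjusted over the list alone (camera adjusted p 0.475). No gene passed among 10 inflammatory cytokine and chemokine genes (Cxcl12 1.12, Cxcl14 -0.88, Cxcl1 1.20, Tgfb1 0.66, camera adjusted p 0.707), 4 T or NK markers (Cd4 1.24, Foxp3 1.67, Cd8a 0.91, Cd3e -0.24, camera adjusted p 0.333) or 5 genes of Wnt, Notch, hedgehog and growth factor signalling (Gli1 -2.14, Lef1 -1.56, Lgr5 0.56, Pdgfb -0.55, camera adjusted p 0.475), and for each of these lists 0 passed when adjusted over the list alone. In these 3 lists, the edgeR test gave Cxcl12, Cxcl14 and Gli1 an unadjusted p under 0.05. With a correlation estimated from the data in place of camera's preset 0.01, 0 lists passed.

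Among the 3 sections on the shared slide, 13 genes passed, 12 of them among the 27, and S100a8 (6.24), Tnc (4.06), Stfa1 (3.76), Gsdmc (2.98) and Krt15 (-4.58) kept their direction and passed. The count was 8 without expanded section 1, 7 without expanded section 2 and 16 without nonexpanded section 2, and those 5 genes passed in each fit that left out a section. The basal keratinocyte list did not pass without expanded section 1 (camera adjusted p 0.0732), without nonexpanded section 2 (0.0550) or on the shared slide (0.0535).

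Cell classes at PI-14 differed in the same directions. Macrophage- or monocyte-like cells made up 26.8% and 29.5% of kept cells in the expanded sections and 10.9% and 2.77% in the nonexpanded sections (edgeR log2 difference 2.03, SE 0.72, adjusted p 0.0488). A cluster led by Lgr5, Igfbp2, Tnc and Pdgfra, the last a marker of fibroblasts, made up 12.4% and 1.66% on average (log2 2.84, edgeR adjusted p 0.0488). T or NK-like cells, at 6.37% ± 0.996 against 0.758% ± 0.345 (SD, n = 2 each), did not pass (log2 3.03, edgeR adjusted p 0.0790). Keratinocyte-like cells, at 23.8% and 26.9% against 45.6% and 82.6%, did not pass either (log2 -1.34, edgeR adjusted p 0.0790). Within the keratinocyte-like class, the nonexpanded sections held mostly a cluster led by Krt15 and Lgr6 (32.9% and 58.9% of kept cells, against 2.72% and 3.38% in the expanded sections) and a cluster led by Lor and Ivl (9.09% and 22.6%, against 3.58% and 4.70%). The expanded sections held mostly a cluster led by Col17a1 and Krt5 (9.10% and 9.54%, against 3.01% and 0.925%) and a cluster led by Gsdmc (8.42% and 9.29%, against 0.617% and 0.206%). The macrophage-like share did not pass on the shared slide (log2 2.11, edgeR adjusted p 0.578) or without expanded section 1 (0.207), expanded section 2 (0.240) or any 1 of the 4 sections at PI-7 (0.0799 to 0.169). It passed without nonexpanded section 1 (log2 3.34) and, at a smaller size, without nonexpanded section 2, the section in pieces (log2 1.37). It also did not pass with the replicate block (0.0526), at resolution 0.5 (0.0624) or 2 (0.0525), with at least 20 transcripts per cell (0.0847) or with cells thinned to 10 (0.0646), and it passed with at least 5 transcripts (0.00800) and with marker counts (0.00220), while an exact two-sided permutation test of 2 against 2 sections cannot go below its value here, 0.333.

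**Figure D2:**
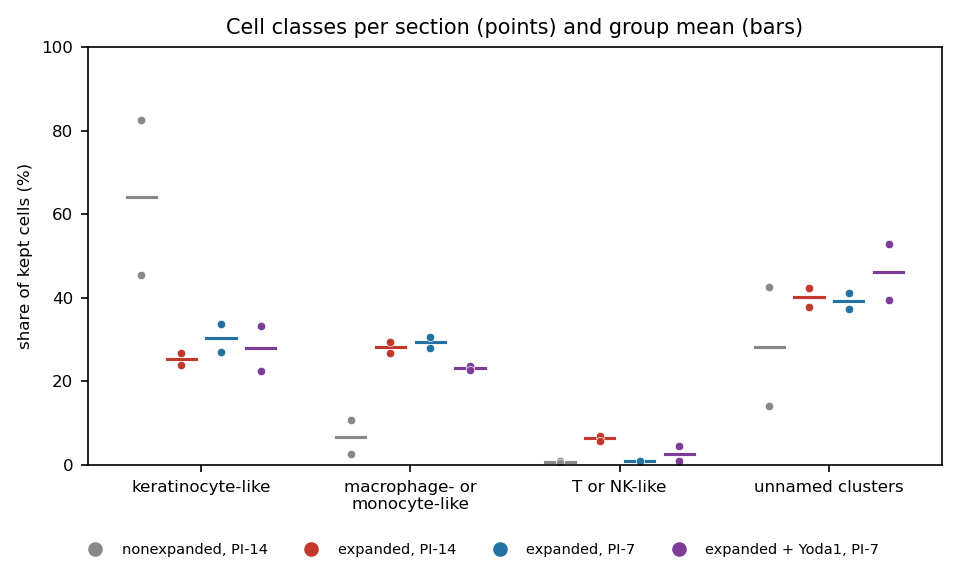
Share of kept cells in percent for 3 named classes and the unnamed clusters together, with a point for each section and a bar for the mean of each group of 2 sections. Macrophage- or monocyte-like cells average 28.2% in expanded and 6.82% in nonexpanded skin at PI-14.

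Summed over keratinocyte-like cells alone, 6 genes rose and 2 fell in expanded skin at PI-14. S100a8 rose by 7.73 on the log2 scale (SE 0.98, 2 sections per group), Lcn2, an iron-scavenging antimicrobial protein, by 4.61 (SE 0.96), Stfa1 by 4.53 (SE 0.65), Gsdmc by 3.55 (SE 0.80) and Fabp5 by 2.99 (SE 0.56). Sprr2a3, named after its value was seen, rose by 3.48 (SE 0.80). Krt15 fell by 3.64 (SE 0.48) and Lgr6 fell by 3.50 (SE 0.64). In these cells nonexpanded sections 1 and 2 held 33 and 3 S100a8 and 24 and 6 Lcn2 transcripts. Expanded sections 1 and 2 held 27163 and 52071 S100a8 and 3968 and 4142 Lcn2 transcripts. The sizes of these 2 changes thus rest on few nonexpanded counts. These 8 genes were all that passed of 99 tested (edgeR, 20 with an unadjusted p under 0.05), and Piezo1 did not pass (-0.91, edgeR adjusted p 0.287). The keratinocyte-like clusters of the groups differed as given above. Summed within the Lor- and Ivl-led cluster alone, S100a8 (8.91, with 9 transcripts in the nonexpanded sections), Stfa1 (5.23), Sprr2a3 (4.51), Gsdmc (3.32), Lcn2 (6.14), Fabp5 (2.50) and Krt15 (-2.38) passed. Within the Krt15- and Lgr6-led cluster only Lcn2 of the 8 genes passed (4.54). There S100a8 (5.03), Stfa1 (2.39), Gsdmc (1.65), Sprr2a3 (1.41), Fabp5 (0.28), Krt15 (-1.84) and Lgr6 (-1.26) did not pass. In keratinocyte-like cells 0 lists passed by camera, at PI-14 or with Yoda1. Without nonexpanded section 1 the count was 20, without expanded section 2 it was 6, and on the shared slide it was 5, with S100a8 (8.03), Stfa1 (4.56), Lcn2 (4.47) and Lgr6 (-4.48) among them but not Gsdmc, Fabp5 or Krt15 (adjusted p 0.0651 to 0.0856). Gsdmc did not pass without expanded section 2 or without either section at PI-7 lacking Yoda1, and Lcn2 did not pass without nonexpanded section 2, while Gsdmc stood at 5.83 without nonexpanded section 1.

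**Figure D3:**
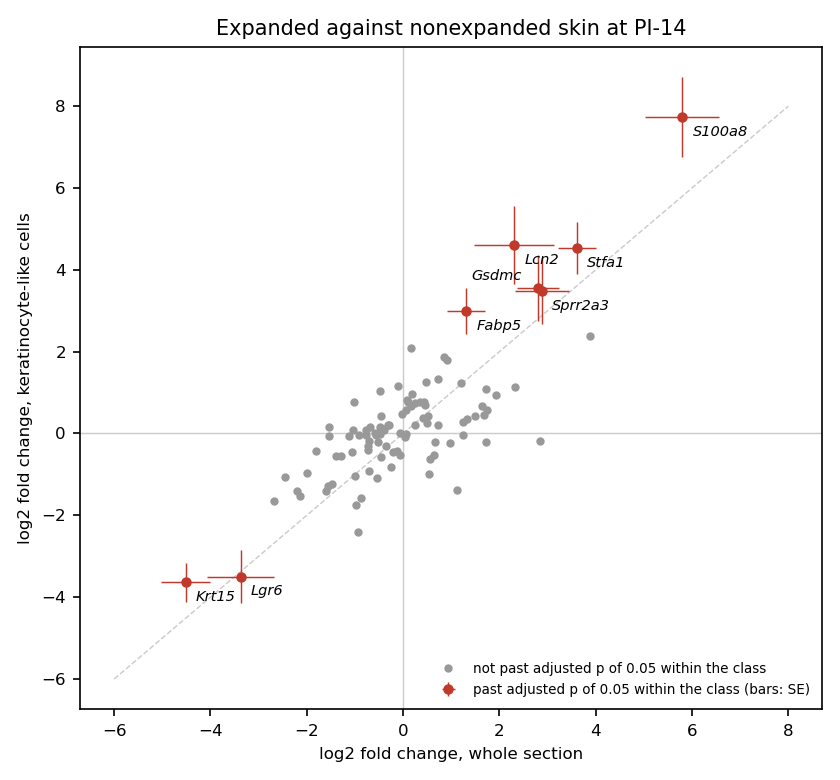
Log2 fold change of each gene in expanded against nonexpanded skin at PI-14, in whole sections on the horizontal axis and in keratinocyte-like cells on the vertical axis. Red points with SE bars are the 8 genes past an adjusted p of 0.05 in keratinocyte-like cells, grey points are the others, and the dashed line marks equal values; S100a8 lies at 5.79 and 7.73.

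In macrophage- or monocyte-like cells at PI-14, Postn rose by 2.97 (SE 0.48), Tnc by 3.26 (SE 0.64) and Igfbp2 by 3.82 (SE 0.68) on the log2 scale, with 2 sections per group. These 3 were the only genes past the test of 99 (edgeR, 18 with an unadjusted p under 0.05), and Csf1r (0.37), Mrc1 (0.40), Cd163 (0.23), Adgre1 (0.60) and Piezo1 (-0.28) did not pass. The nonexpanded sections held 282 and 27 such cells, with 49 Postn, 11 Tnc and 3 Igfbp2 transcripts among 7055, against 19050, 5552 and 2191 among 341631 in the expanded sections. The ratio of the pooled shares was 8.03 for Postn, 10.4 for Tnc and 15.1 for Igfbp2, the last with an exact 95% interval of counting error of 5.15 to 73.2. The 3 genes are also leading genes of the Pdgfra-led clusters, and 0 genes passed with transcripts over the nucleus only (edgeR, 11 with an unadjusted p under 0.05) or on the shared slide (4 with an unadjusted p under 0.05). Over the nucleus Postn was still higher by 1.90 (SE 0.51, edgeR adjusted p 0.0879), Tnc by 1.62 (SE 0.71) and Igfbp2 by 2.76 (SE 1.22), with 19, 7 and 1 transcripts in the nonexpanded sections against 3065, 884 and 271. Tnc did not pass without expanded section 2 or without nonexpanded section 1, and Igfbp2 did not pass without nonexpanded section 1, with counts of 2 in both fits. The count was 5 without Yoda1 section 2 and 6 without expanded section 2 at PI-7. Of the 11 lists, T or NK markers moved up (camera adjusted p 0.0355) and basal keratinocyte genes down (camera adjusted p 0.0376), both with an adjusted p of 0.791 under an estimated correlation. The nonexpanded sections held 0 Cd3e, 0 Foxp3, 1 Cd8a and 4 Cd4 transcripts in these cells, and for the 4 genes together the ratio of the pooled shares was 4.60 (exact 95% interval of counting error 1.96 to 14.2).

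The comparison at PI-7 asked how expanded skin with Yoda1 differs from expanded skin without it. No gene passed the test of 100, and the values here describe the genes with the smallest p. Krt15 was lower with Yoda1 by -1.63 on the log2 scale (SE 0.45, edgeR adjusted p 0.529), at 1848 ± 372.8 against 5721 ± 2529 CPM (SD, n = 2 each). The glucose transporter gene Slc2a1 was higher by 1.13 (SE 0.43), the angiogenic factor gene Vegfa by 0.85 (SE 0.39), and the cytokine genes Cxcl1 and Il6 by 1.27 (SE 0.59) and 1.06 (SE 0.53). Cd4 was higher by 1.24, Tnc by 0.85 and Stfa1 by 0.58, while Lor (-1.14) and Scd1 (-1.15) were lower. Piezo1 did not differ beyond the spread between sections (-0.17, SE 0.32, edgeR adjusted p 0.937). By edgeR 0 genes passed and 2 had an unadjusted p under 0.05, and by DESeq2 1 passed, Krt15, and 5 had one.

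Of 14 glycolysis and hypoxia genes, 12 were higher with Yoda1, among them Slc2a1, Vegfa, Slc2a3 (0.73) and Hif1a (0.39), but 0 passed, also when adjusted over the list alone (mean log2 fold change 0.33, camera adjusted p 0.0661). Of 10 inflammatory cytokine and chemokine genes, 8 were higher, among them Cxcl1, Il6, Il33 (0.62) and Cxcl10 (1.30), with a camera adjusted p of 0.0806. The T or NK markers Cd4, Cd8a (1.39), Foxp3 (0.97) and Cd3e (0.92) were all higher (camera adjusted p 0.0806), beside a T or NK-like share that was highest in Yoda1 section 2. Without that section Cd8a stood at -0.67, Cd3e at -0.53 and Cxcl10 at -1.27. The basal keratinocyte genes Krt15, Col17a1 (-0.37) and Krt5 (-0.33) were lower and Krt14 was not (0.04), and 1 gene passed when adjusted over the list alone (camera adjusted p 0.0661). The suprabasal genes Lor, Krt10 (-0.56), Krt1 (-0.22) and Ivl (-0.16) were all lower (camera adjusted p 0.0661), as were the 5 macrophage markers, among them Cd68 (-0.71), Cd163 (-0.34), Mrc1 (-0.29) and Adgre1 (-0.15; camera adjusted p 0.0806). Of the lipid metabolism genes, 6 of 7 were lower, among them Scd1, Fasn (-0.38) and Acaca (-0.27), while Fabp5 was higher (0.60; camera adjusted p 0.117). Matrix genes (Tnc, Col17a1, Col4a1 0.32, Postn 0.02, camera adjusted p 0.931), signalling genes (Gli1 1.05, Pdgfa 0.50, Lef1 0.86, Pdgfb 0.53, camera adjusted p 0.344), macrophage state genes (camera adjusted p 0.912) and mechanical and YAP-TEAD response genes (Yap1 -0.33, Vcl 0.31, Piezo2 0.36, camera adjusted p 0.442) did not pass. For the last list camera pointed down while the mean (0.03) and median (0.02) lay above 0, and for the macrophage state list camera pointed down and fry up, with a mean of -0.01. In each list but the basal one, 0 genes passed when adjusted over the list alone, and 0 of the 11 lists passed with the preset or an estimated correlation.

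On the slide that the Yoda1 sections shared with expanded section 2, 0 genes passed by edgeR and 1 had an unadjusted p under 0.05. There Krt15 stood at -1.18, Slc2a1 at 0.77, Vegfa at 0.40, Cxcl1 at 1.65 and Il6 at 1.19. On that slide the inflammatory list had a mean of 0.62 and the macrophage list a mean of -0.47. A correlation estimated from these 3 sections in 2 groups took values such as 1, 0 and -0.333 across the lists. Camera with that correlation could therefore not decide about any list there. The glycolysis and hypoxia list had a mean of 0.08 there. Each of 3 fits that left out a section gave 3 lists past the test, namely those without Yoda1 section 1, without expanded section 1 at PI-7 and without expanded section 2 at PI-14. The fit without expanded section 2 at PI-7 gave 2 and the fit without nonexpanded section 1 gave 1.

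The shares of cell classes did not differ past the test with Yoda1. Macrophage- or monocyte-like cells made up 23.3% ± 0.654 with and 29.4% ± 1.88 without Yoda1 (log2 -0.34, edgeR adjusted p 0.991), and keratinocyte-like cells 27.9% ± 7.57 and 30.4% ± 4.62 (log2 -0.12; SD, n = 2 each). T or NK-like cells made up 0.916% and 4.54% in Yoda1 sections 1 and 2 against 0.896% and 1.06% without it (log2 1.48, edgeR adjusted p 0.981). A cluster led by Cxcl1 and Il6 made up 10.1% ± 6.27 with and 2.94% ± 0.505 without Yoda1 (SD, n = 2 each) and did not pass (log2 1.78, edgeR adjusted p 0.981). Of the 16 classes and clusters, 0 had an unadjusted p under 0.05 by edgeR, and DESeq2 was not run on shares. On the shared slide the macrophage-like value was -0.40, the T or NK-like value 1.36 and the keratinocyte-like value 0.04.

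In keratinocyte-like cells with Yoda1, Krt15 was lower by -1.78 (SE 0.45), the progenitor marker Cd34 lower by -2.53 (SE 0.80) and Col4a1 higher by 1.45 (SE 0.50) on the log2 scale, with 2 sections per group, but 0 of 99 genes passed by edgeR, 5 had an unadjusted p under 0.05, and DESeq2 gave 2, Krt15 and Col4a1. In macrophage- or monocyte-like cells, the keratinocyte genes Krt10 (-2.53, SE 0.64), Lor (-2.16, SE 0.58) and Krt1 (-1.99, SE 0.58) had the smallest p but did not pass (edgeR adjusted p 0.0925 to 0.108). There, 0 of 99 genes passed by edgeR, 8 had an unadjusted p under 0.05, and DESeq2 gave 1, Krt10. With the replicate block 4 genes passed by edgeR, 1 higher and 3 lower. Suprabasal (camera adjusted p 1.4e-05) and basal keratinocyte genes (0.0226) moved down in these cells and T or NK markers up (0.0226), each with an adjusted p of 0.507 under an estimated correlation. Such keratinocyte transcripts also made up 2.36% and 2.46% of the transcripts outside cells far from keratinocyte-like cells in the Yoda1 sections and 4.59% and 8.08% in the sections without it. Without expanded section 1 at PI-7, or without Yoda1 section 2, 3 genes passed in macrophage-like cells, and without nonexpanded section 1 or nonexpanded section 2, 1 passed. In keratinocyte-like cells 2 passed without nonexpanded section 1.

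Under the main setting, macrophage-like cells lay nearer to keratinocyte-like cells with Yoda1 than without it. The median distance to the nearest such cell was 142.8 and 112.4 µm in Yoda1 sections 1 and 2 and 206.1 and 186.1 µm in sections 1 and 2 without Yoda1, a difference of -68.5 µm (127.6 ± 21.5 against 196.1 ± 14.1; SD, n = 2 each). The exact two-sided permutation p was 0.333, the smallest that 2 against 2 sections allow. At PI-14 the medians were 141.3 and 142.3 µm in expanded skin and 284.2 and 17.5 µm in nonexpanded skin, the last from 27 cells of the section in 4 pieces, a difference of -9.03 µm that was smaller than the spread (exact two-sided permutation p 1). It was 124.3 µm without nonexpanded section 1 and -142.4 µm without nonexpanded section 2. The distance depends on how cells are named. With cells named by marker counts the difference with Yoda1 was 22.0 µm.

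Across the 100 genes, the log2 fold change with Yoda1 at PI-7 tracked that with expansion at PI-14 (Pearson r 0.470, 95% interval 0.301 to 0.610, Spearman rho 0.433), and 67 genes had the same sign. Krt15, Lor and Scd1 were lower in both comparisons, and Tnc and Stfa1 higher, although with Yoda1 none of them passed. The macrophage genes went opposite ways. Mrc1, Csf1r, Cd163 and Adgre1 rose at PI-14, but the 5 macrophage markers were all lower with Yoda1 (mean -0.32), none past the test. No section belongs to both comparisons, genes are not independent replicates, and no p-value is given. On the shared slides alone r was 0.215 with rho 0.177 and 54 genes of the same sign. Among 46 genes with at least 100 counts in every section r was 0.790. That filter drops the 5 macrophage markers, which had 13 to 62 counts in nonexpanded section 2, and also S100a8 (9) and Tnc (29). The higher r therefore describes a different set of genes and not a closer agreement of the whole panel. Without expanded section 1 at PI-7 r was 0.218, again with 54 genes of the same sign.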

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

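The test in keratinocyte-like cells was chosen only after its result was seen, and the other tests of the pattern weighed here before. Krt1, Krt10 and Lor are made by keratinocytes of the upper epidermis, yet they were found among transcripts that lay outside all cells and over 100 µm from any keratinocyte-like cell. The main comparisons do not use this part of the data, and only the alternative with all transcripts counts it. Their share of these transcripts was 2.36% and 2.46% in Yoda1 sections 1 and 2, against 4.59% and 8.08% in expanded sections 1 and 2 at PI-7 without Yoda1. At PI-14 it was 6.21% and 6.77% in expanded sections 1 and 2 and 3.20% and 12.5% in nonexpanded sections 1 and 2.

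In macrophage-like cells, the same 3 genes were lower in the Yoda1 sections than in expanded skin without Yoda1 (mean log2 ratio -1.98, SE 0.83), although no single gene passed the test. With cells named by clusters, keratinocyte-like cells lying closer to macrophage-like cells without Yoda1 are argued against. The mean log2 ratio was -2.12 (SE 0.71) in macrophage-like cells over 100 µm away from them. Such far cells were most of the class, as in 2070 of 2956 cells of expanded section 2 without Yoda1. With cells named by marker counts the median distances were 44.6 and 30.7 µm without Yoda1, against 42.6 and 76.8 µm with it. The ratio in far cells was not computed for that naming, so this explanation stays open there. Transcripts spread through the section outside cells may be the source, since the 3 genes among such transcripts had a mean log2 ratio of -1.51 (SE 0.33) between the same groups. A lower output by keratinocyte-like cells with Yoda1, the difference that the design names, stays open, because there the mean log2 ratio was -0.66 (SE 0.26), with fitted values of -0.29 (SE 0.39) for Krt1, -0.62 (SE 0.41) for Krt10 and -1.23 (SE 0.48) for Lor, none past the test. This is a smaller drop than in macrophage-like cells, but the gap of -1.32 has an SE of 0.91.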

How the results depend on the processing

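The tests with crossed repeat numbers, in Pecam1-led and Pdgfra-led clusters, of lists within classes and of lists on the shared slide with an estimated correlation were chosen only after the data were seen. Of single genes named at PI-14, 381 of 432 values under alternatives other than leaving out a section kept their direction and their side of the threshold, 40 lost the call, 5 gained one and 6 turned. For Yoda1, 348 of 360 did so, 1 gained a call and 11 turned. For lists these numbers were 81 of 88 at PI-14 and 79 of 88 for Yoda1, for class shares 17 of 24 and 22 of 24, and for genes within classes 111 of 127 and 72 of 90. S100a8, Stfa1, Tnc, Gsdmc and Krt15 passed in whole sections at PI-14 under every alternative run for single genes, those that left out a section included. The causes of the changes listed here were not tested, except that fits on 3 or 4 sections have fewer samples. Planned tests within fibroblast-like and endothelial-like cells were not run, because these could not be named, and the macrophage-like test at PI-14 with at least 20 transcripts per cell was not run, because too few cells were left. Depth limits most of all the nonexpanded sections, where the median cell held 8 and 5 transcripts.

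The 27 genes called at PI-14 became 11 with the 4 sections of the comparison only (11 of them among the 27) and 13 on the shared slide (12 among the 27). The 2 lists became 4 with nucleus transcripts only, 4 with fry and 0 with a correlation estimated from all sections (camera, 0 at an unadjusted p under 0.05). The lists past the test also differed on the shared slide, where an estimated correlation rests on 3 sections and cannot decide. Genes far from the threshold changed sign, namely Col4a1 to 0.0015 with DESeq2, 0.0926 without TMM and 0.12 on the shared slide, and Cd3e to 0.12 without TMM, 0.0683 with nucleus transcripts only and 0.0452 with the replicate block. The 1 named class with a changed share became 2 with at least 5 transcripts and 0 with at least 20, on the shared slide, at resolution 0.5 or 2 and with cells thinned to 10 transcripts (edgeR, 0 to 3 with an unadjusted p under 0.05).

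For Yoda1, 0 genes became 1 with DESeq2 (5 with an unadjusted p under 0.05), and 0 lists became 2 with nucleus transcripts only, 2 without TMM and 1 with the 4 sections only. The lists past the test also differed on the shared slide, where an estimated correlation again cannot decide. Postn turned to -0.0413 with DESeq2, -0.0344 without TMM, -0.18 with nucleus transcripts only, -0.11 with all transcripts, -0.0443 with the replicate block and -0.0653 on the shared slide. Krt14 turned to -0.0747 with nucleus transcripts only and Ivl to 0.15 with all transcripts, and on the shared slide Krt5 turned to 0.0183, Fasn to 0.0778 and Col4a1 to -0.0479. The direction of the test turned for the macrophage state list with fry (mean -0.0139) and for the matrix list with all transcripts (mean 0.0910). The keratinocyte-like share turned to 0.0428 on the shared slide and the macrophage-like share to 0.0101 with marker counts. The correlation of the comparisons across genes was 0.215 on the shared slides and 0.790 among genes with at least 100 counts, which leave out the macrophage markers.

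Within keratinocyte-like cells, 8 genes at PI-14 became 17 with DESeq2 (8 of them shared) and 5 on the shared slide, and 0 genes for Yoda1 became 2 with DESeq2 and 1 with nucleus transcripts only. Within macrophage-like cells, 3 genes at PI-14 became 0 with nucleus transcripts only, 0 on the shared slide, 5 with at least 5 transcripts and 7 at resolution 2, and 0 genes for Yoda1 became 1 with DESeq2 and 1 with at least 5 transcripts. In Pdgfra-led clusters 0 genes for Yoda1 became 5 with DESeq2 and 2 with nucleus transcripts only. In Pecam1-led clusters 7 genes at PI-14 became 0 on the shared slide, and 2 genes for Yoda1 became 1 with DESeq2 and 1 without the filter. The distance at PI-14 turned to 0.0801 µm with at least 5 transcripts, and for Yoda1 to 22.0 µm with marker counts.

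Replicate numbers are shared between groups, but sections with the same number did not deviate together (correlation -0.193 at PI-14 and -0.194 at PI-7). Between groups at different time points the same correlation ranged from -0.372 to 0.319. These values therefore cannot settle whether the numbers pair the sections, and the labels do not say. With the replicate block 25 genes passed at PI-14 (25 among the 27) and 0 for Yoda1, 2 and 0 lists, and 0 named classes changed share at PI-14 (edgeR, 3 with an unadjusted p under 0.05). Within classes the block gave 7 genes in macrophage-like cells at PI-14 and 4 for Yoda1, 4 in Pdgfra-led clusters for Yoda1, and 3 at PI-14 and 1 for Yoda1 in Pecam1-led clusters, and it changed no other count by over 1.5 times. With crossed repeat numbers as the block in the 4 sections of the comparison, added after the data were seen, 10 genes passed at PI-14, against 11 in those 4 sections without a block, and 0 for Yoda1 in both (edgeR, 10 with an unadjusted p under 0.05 with the block and 6 without).

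With each section left out in turn, the count at PI-14 ranged from 7 to 33 genes, from 1 to 4 lists and from 0 to 3 classes, with 6 to 20 genes in keratinocyte-like cells, 2 to 6 in macrophage-like cells and 2 to 17 in Pecam1-led clusters. For Yoda1 it ranged from 0 to 3 lists, 0 to 2 genes in keratinocyte-like cells and 0 to 3 in macrophage-like cells, Pdgfra-led clusters and Pecam1-led clusters each. At PI-14, Cd3e ranged from -1.01 to 1.03, Col4a1 from -0.41 to 0.20, the inflammatory list mean from -0.25 to 0.34 and the distance from -142.4 to 124.3 µm. For Yoda1, values that did not pass ranged from -0.0026 to 1.39 for Tnc, -0.78 to 0.0015 for Col17a1, -0.67 to 0.12 for Krt5, -0.27 to 0.43 for Krt14, -0.54 to 0.14 for Ivl, -0.43 to 0.12 for Adgre1, -0.67 to 2.21 for Cd8a, -0.12 to 1.58 for Foxp3, -0.53 to 1.63 for Cd3e and -1.27 to 2.17 for Cxcl10. They ranged from -0.77 to 0.17 for Fasn, -0.50 to 0.0026 for Acaca, -0.39 to 0.80 for Col4a1, -0.32 to 0.29 for Postn, -0.17 to 0.67 for Vcl, -0.31 to 0.82 for Piezo2, -0.46 to 0.0699 for Piezo1, -0.36 to 1.52 for Lef1 and -0.12 to 0.98 for Pdgfb. The means ranged from -0.29 to 1.82 for the T or NK list, -0.0701 to 0.0326 for macrophage states, -0.37 to 0.61 for matrix genes and -0.43 to 0.38 for mechanical genes. The keratinocyte-like share ranged from -0.43 to 0.13, the T or NK-like share from -0.0942 to 2.21 and the correlation across genes from 0.218 to 0.601. The lowest values of Cd8a, Foxp3, Cd3e, Cxcl10 and Lef1 were those without Yoda1 section 2.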

Other observations

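The tests of the clusters led by Pecam1 or Pdgfra, the test without nonexpanded section 2, both tests of cell shares and the test in single keratinocyte-like clusters were chosen only after results were seen, and the test of nuclear transcripts before. Cells of the Pecam1-led clusters, Pecam1 being an adhesion molecule of blood vessel lining, differed between expanded and nonexpanded skin at PI-14. Postn rose by 2.31 on the log2 scale (SE 0.36, 2 sections per group), Tnc by 4.10 (SE 0.86), the proliferation marker Mki67 by 4.71 (SE 1.03), the macrophage genes Mrc1 by 2.06 (SE 0.49) and Csf1r by 2.29 (SE 0.56), and Igfbp2 and Lgr5 by 4.36 and 3.51. These 7 genes were all that passed of 91 (edgeR, 25 with an unadjusted p under 0.05). Among 7953 transcripts of the nonexpanded sections, Mki67, Igfbp2 and Lgr5 had 1 each, Tnc 4, Csf1r 15, Mrc1 18 and Postn 72, so the first 3 values rest on almost no counts (ratios of pooled shares 28.7, 21.4 and 12.4, exact 95% intervals of counting error 5.12 to 1137, 3.81 to 848 and 2.20 to 493). Nonexpanded section 2 held 0 transcripts of Mki67, Igfbp2, Lgr5 and Csf1r in these clusters, 1 of Tnc, 2 of Mrc1 and 8 of Postn. The nonexpanded values therefore rest mostly on section 1. With the replicate block only Postn, Tnc and Mki67 passed. Markers of other cells moved with them: all 5 macrophage markers were higher (mean 2.29, camera adjusted p 0.0828), among them Cd163 (2.20) and Adgre1 (3.56), as were the leukocyte gene Ptprc (1.90) and Pdgfra (1.48), none of the last 4 past the test, while Pecam1 stood at -0.14. Whether other cells, or transcripts of neighbouring cells, lie in these clusters is open, and with nuclear transcripts only 8 genes passed, among them Postn, Tnc, Mki67, Mrc1 and Csf1r. On the shared slide 0 passed by edgeR, with 4 at an unadjusted p under 0.05. The count was 2 without either Yoda1 section, 3 without expanded section 1 at PI-14, 4 without nonexpanded section 1 (Tnc 2.23 and Mrc1 1.36), 12 without expanded section 2 at PI-14, and 15 and 17 without expanded sections 1 and 2 at PI-7.

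With Yoda1, Krt10 (-2.57) and Krt1 (-2.22) were past the test and lower in the Pecam1-led clusters, of 91 genes and 4 with an unadjusted p under 0.05 (edgeR). Neither passed without Yoda1 section 1, Yoda1 section 2 or expanded section 2 at PI-7, each of which gave 0 genes (-1.65 and -0.97 without the last), Krt1 did not pass with the replicate block (edgeR adjusted p 0.151), and they are the keratinocyte genes weighed with the transcripts outside cells. In the Pdgfra-led clusters, 0 of 100 genes passed by edgeR and 9 had an unadjusted p under 0.05, while DESeq2 gave 5. The smallest p there belonged to the progenitor marker Ly6a (-1.08), Lor (-2.57), Krt10 (-2.62) and the hypoxia factor gene Epas1 (1.75), with an edgeR adjusted p of 0.0705. Without Yoda1 section 1 or without expanded section 1 at PI-7, 3 genes passed. The suprabasal list moved down with Yoda1 in the Pecam1-led clusters (camera adjusted p 5.4e-07, with an estimated correlation 0.162) and in the Pdgfra-led clusters (camera adjusted p 0.00300, with an estimated correlation 0.697).

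Higher Postn, Tnc and Igfbp2 in macrophage-like cells of expanded skin at PI-14 may not reflect transcripts that macrophages make. The few macrophage-like cells in nonexpanded section 2 are argued against as the cause, because 3 of the 3 genes still passed without that section, by 2.84 to 3.66 on the log2 scale. Transcripts of neighbouring cells inside the outline of a macrophage-like cell remain a candidate source, since relative to all genes the 3 lay over the nucleus less often in macrophage-like than in Pdgfra-led cells of the expanded sections (mean log2 ratio -0.87, range -1.14 to -0.69), as that source needs. With nuclear transcripts alone none of the 3 passed, since the values were smaller (1.62 to 2.76, against 2.97 to 3.82) and their SE larger (0.51 to 1.22, against 0.48 to 0.68). They stayed above 0, but the 3 genes were picked from counts that include these nuclear transcripts. The nonexpanded sections held 19 of Postn, 7 of Tnc and 1 of Igfbp2 over the nucleus. The nuclear values therefore cannot decide between the 2 sources. Expression by macrophages themselves, with expansion as the design names it, thus stays open.

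Genes that changed between whole sections at PI-14 could follow the shares of cell classes, since sections with fewer macrophage-like cells hold fewer macrophage transcripts. For Stfa1, S100a8, Gsdmc and Sprr2a3 a different share of keratinocyte-like cells is argued against, because that share was lower in expanded skin (25.4% against 64.1% of kept cells). Their mean log2 fold change was 3.77 in whole sections and 4.82 within that class. These 2 means rest largely on the same transcripts, so the second is no separate test. The class differed less by its share of transcripts than by its share of cells. It held 704283 of 1213851 and 901334 of 1477864 panel transcripts in the expanded sections, against 86040 of 135833 and 29521 of 36284 in the nonexpanded sections. Different keratinocyte-like clusters in each group are argued against as the whole cause, transcripts of neighbouring cells aside, because the mean was 5.49 within the Lor- and Ivl-led cluster, where 4 of 4 passed (SE 0.78 if the genes move together), but a part stays open: within the Krt15- and Lgr6-led cluster the mean was 2.62 (SE 1.33 likewise) and 0 of the 4 passed (edgeR, 2 with an unadjusted p under 0.05), and the other clusters had too few nonexpanded cells to be tested. The clusters were formed on the same genes, and transcripts of neighbouring cells were not removed. Transcripts of other keratinocyte-like clusters inside these outlines therefore stay open too. For Csf1r, Cd163, Mrc1 and Adgre1 the mean within macrophage-like cells was 0.40, against 1.78 in whole sections, which cannot be told apart from a smaller share of such cells, because the cells were named by these very markers. How much of the class shares is itself set by depth and by the part of the skin in each section, nonexpanded section 2 being 4 pieces of which 3 were mostly keratinocyte-like cells, stays open, as does expansion itself, which the design names and no test here addressed.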
